A study of Mus musculus with 20 samples.

How the data were processed

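Histone H3 acetylated at lysine 36 (H3K36ac) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in cultured female mouse cells that the labels call TTF, taken here as tail-tip fibroblasts, from a cross of the C57BL6 and CAST strains. The series held 20 samples, of which 10 were ChIP libraries with deposited peak lists and 10 were input samples, for which no file was used here. The ChIP libraries formed 5 groups of 2, taken from the sample titles. The first set held wild type (WT, replicates 1 and 2) and Sirt7 knockout (KO, replicates 1 and 2). The second set held KO clones 9 and 22, the same clones with SIRT7 added back (KO+WT, clones 9 and 22), and clones 5 and 7 of a line labelled HY, an abbreviation that the sources used here do not spell out. WT was measured in the first set and HY and KO+WT in the second, so values were compared within a set. The labels do not say that libraries of a group came from separate cultures, so a p-value measured only the spread between these libraries, which may be technical.

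The labels conflicted in 2 places. The genotype tag of the libraries titled wild type names the knockout, and that of the knockout inputs names the wild type; the titles were used for the groups. The design text of the series names H2AX and gammaH2AX, while the labels of all libraries name H3K36ac. The clone of the first-set KO libraries was read from the peak names inside the files (replicate 1, clone 22; replicate 2, clone 9), since the labels do not give it, and was used only where clones are compared.

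Upstream tools were FastQC 0.11.3, Trimmomatic 0.36, Bowtie2 2.2.9, SAMtools 0.1.19, deepTools 2.4.2 and MACS2 2.2.7.1 on mm10, per the submitters' processing notes. The deposited files were 42 MACS2 broad peak lists. Per library there were 3 read classes, named genome1, genome2 and unassigned, that is, reads assigned to either parental genome or to neither. A list of all reads was also deposited for the 6 second-set libraries, and 6 lists called on pooled libraries for the first set. The tool that split reads by parent, which strain was genome1, the control behind each peak and the calling threshold are not given in the sources used here. Each peak carries the authors' fold enrichment, a linear ratio. It also carries the −log10 p and −log10 q values that the authors' caller assigned, and the lowest deposited −log10 q was 1.00. These values were used only to describe, rank or filter peaks within a list. The protocol in the labels names spiked-in nucleosomes, but the peak lists hold no read numbers. The depth of each library was therefore unknown, no counting interval for it was given, and a longer list can come from more reads, better enrichment or more acetylated chromatin.

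The unassigned list of each library was the main list. Overlapping peaks were merged on the autosomes and X. Covered length was summed in Mb, and 21631 protein-coding genes (966 X-linked, 20665 autosomal) were scored from RefSeq gene positions on GRCm38, the assembly that mm10 stands for. The gene table gives no strand or transcription start, so the planned promoter window was replaced by windows of 1 kb to either side of both gene ends; a gene had a peak where at least 1 bp of a peak fell in either window. The X share was the log2 ratio of the percent of X-linked genes to the percent of autosomal genes with a peak. The X allelic skew was the log2 ratio of genome1 to genome2 coverage on X minus that on autosomes. A gene was called gained when it had a peak in both libraries of the first-named group and in neither of the other, and lost in the reverse case. Regions of the genome1 lists on X were merged across libraries over gaps of up to 2 kb.

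Library values were compared on the log2 scale by exact permutation tests, two-sided, for which the smallest possible p with 2 libraries against 2 was 0.333, so that no such test could reach 0.05. Counts of gained and lost genes were set beside the counts from the other ways of parting the same 4 libraries. For the 20 gene lists, Fisher's exact test, two-sided, compared the gained (or lost) share of a list with that of all other genes that could have been gained (or lost), with Benjamini-Hochberg adjustment over 40 tests per comparison and a threshold of 0.05. These tests run across genes, which are not replicates. The lists covered the X inactivation centre, genes that escape X inactivation, imprinted genes, ribosomal proteins, rRNA synthesis and nucleolus, sirtuins and histone deacetylases, histone acetyltransferases, the DNA damage response, X-linked epigenetic regulators, the cell cycle, the interferon response, Hox genes, housekeeping genes, and markers of fibroblasts and of 6 other cell types: keratinocytes and other epithelium, immune cells, endothelium, muscle, neural cells and melanocytes, and pluripotent and germ cells.

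The groups, tests, lists, the alternatives other than those named below as added, and the rule for named genes were fixed before the data were examined. The rule took, per comparison and direction, the 10 autosomal and 5 X-linked genes with the highest −log10 q in the weaker of the 2 libraries, Sirt7, Xist, and up to 4 switched members of each list. Many genes so taken in the second set had a peak that reached the window in one group and ended just outside it in the other. The rule was therefore applied again to genes whose other group had no peak within 2.5 kb of either end, and the genes named as strongest are these. List members that fail this check are marked in the text, and those named under an alternative setting were not put to it. Further names are marked as chosen after their values were seen. Some genes that these rules or lists would name are not reported here.

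Alternatives were peaks with a −log10 q of at least 5, equal numbers of strongest peaks per library of a set (15575 in the first, 35729 in the second), the union of the 3 read classes, the lists of all reads, the pooled lists, windows of 2.5 kb, coverage of at least 50 percent of a window, the number of X-linked genes in place of Mb for the skew, the replicate number or clone as a block, and leaving out each library. Added after seeing the data were whole gene spans, the median over autosomes as reference of the skew, a crossed block, another background for X-linked genes, HY against all KO-derived libraries, a −log10 q of at least 5 for genome1 regions on X, the check within 2.5 kb, and the demand that a gene lack a peak of unassigned, genome1 and genome2 reads in the other group. In the second set the block was the clone, which the labels give: deviations of the same clone from the group means over 517 bins of 5 Mb had r = 0.465 in KO and KO+WT. The first-set replicate numbers gave r = -0.125.

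The counts were tested on simulated data for KO against WT over 21631 genes, with 200 genes planted as gained among 6000 with a peak in all libraries and 5% of peaks missed per library. The procedure called 175 of the 200 as gained (87.5%), and 92.6% of the 189 with no neighbouring peak, against 90.2% that the missed peaks allow; 96 other genes were also called, and a skew of -4 was returned as -4. Of 200 random lists, 6 had p below 0.05. The skew check tested only the arithmetic. Both simulated groups shared the 6000 genes and the share of missed peaks, while the real KO and WT lists differed in length. False gained calls from unequal lists were therefore not tested. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.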

Results

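Acetylation of lysine 36 of histone H3, a mark of active promoters, was profiled in female mouse tail-tip fibroblasts with and without SIRT7, a deacetylase of the sirtuin family. The series concerns SIRT7 and dosage compensation of the X chromosome, and the hybrid cross allowed peaks to be called separately on reads of the parental genomes, named genome1 and genome2, whose strain is not given in the sources used here. The 10 ChIP libraries fell into 5 groups of 2: WT and KO in a first set, and KO, KO with SIRT7 added back (KO+WT) and HY in a second set. Unassigned reads gave between 15575 peaks (WT replicate 2) and 76632 peaks (KO clone 22, second set) per library. The numbers of reads behind these lists were unknown. Base pairs under peaks overlapped with a median Jaccard index of 0.399 in the 5 pairs of libraries of the same group, 0.375 in the 16 pairs of other groups of the same set and 0.227 in the 24 pairs across sets. The highest index, 0.539, was that of KO clone 9 and KO+WT clone 9.

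The targeted gene, Sirt7 (chromosome 11, 120618371 to 120625014), had no peak of unassigned reads within its span in either WT or either first-set KO library. In the second set it had peaks in all 6 libraries, and in KO+WT these were among the strongest of the whole list. The peak at 120620645 to 120620856 had the highest −log10 q of the 52587 peaks of all reads in KO+WT clone 9 (73704, fold enrichment 15.2). At nearly the same place, 120620648 to 120620855, KO+WT clone 22 had the second highest of its 35363 peaks (19134, fold 10.4). A further narrow peak, at 120624701 to 120624983 in clone 9, ranked 6 in that list. In the same clones without added SIRT7 the peak near 120620650 had a −log10 q of 69.7 in clone 9 and 43.2 in clone 22, and ranked 1722 and 4075. In HY it had a −log10 q of 184 in clone 5 (fold 27.3, rank 571) and 26.6 in clone 7 (rank 7038). Fold and q are the authors' values for each peak and order peaks within a list, and between lists of different lengths they show no change. These peaks were singled out after their values were seen. A peak of a histone mark does not check whether the gene was disrupted, and the altered part of Sirt7 is not given in the sources used here. It is not known whether the reads of the KO+WT peaks came from the gene or from the added SIRT7 sequence, so these values are not a measure of the mark at the gene.

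In all 10 libraries the X chromosome carried its peaks on genome2. Per library, 207 to 2015 genome2 peaks lay on X against 18 to 177 genome1 peaks, and the X allelic skew ranged from -5.64 to -3.28 on the log2 scale. Xist (X, 103460373 to 103483233), the RNA that coats the inactive X, was the mirror image at its ends: it had a genome1 peak there in 10 of 10 libraries and a genome2 peak in 0. Within the gene a genome2 peak lay in 1 library. Of the 21 listed genes that escape X inactivation, 8 had a genome1 peak at an end in at least 6 libraries. These were Xist, Pbdc1 (10 libraries), Ddx3x (9), Eif2s3x (8), Kdm6a (7), Kdm5c (6), Jpx (6) and 5530601H04Rik (6), and the other 13 had none at an end in any library, though one lay within the gene in 10 libraries at Firre and Ftx, 6 at Car5b, 3 at Mid1 and 1 at Bcor and at Syap1. Usp9x and Ogt had a genome2 peak in 10 libraries and a genome1 peak in 0.

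**Figure D1:**
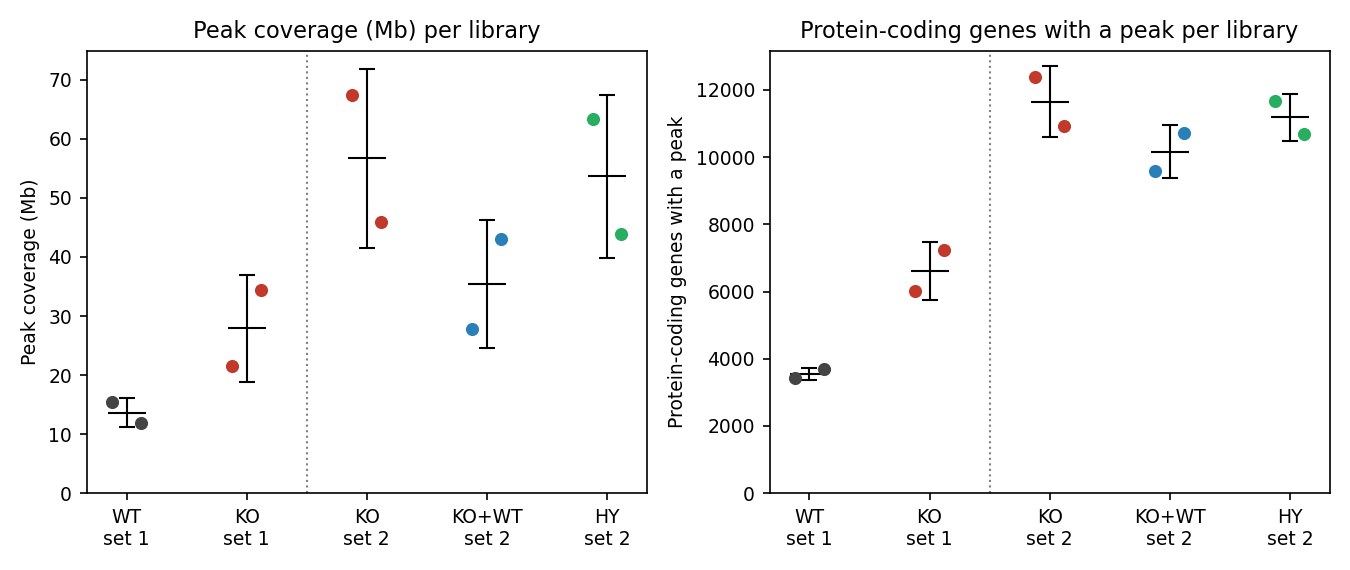
Length covered by peaks of unassigned reads in Mb (left) and protein-coding genes with a peak within 1 kb of a gene end (right); each point is a library, the bar and whiskers are the mean and SD of the 2 libraries, and the dotted line parts the first set from the second. KO libraries had 6011 and 7227 genes with a peak in the first set, against 3431 and 3684 in WT.

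The comparison of KO with WT asked what loss of SIRT7 did to the mark. KO libraries had a peak at 6619 ± 860 protein-coding genes (SD, n = 2) and WT libraries at 3558 ± 179 (n = 2), a ratio of 1.85, and peaks covered 27.9 ± 9.09 Mb in KO against 15.4 and 11.9 Mb in the 2 WT libraries, a ratio of 2.01. In all, 1836 genes had a peak in both KO and neither WT library (gained) and 27 the reverse (lost), both counted in the lists of unassigned reads. Among the gained genes with the strongest peaks were Tsc1, a brake on mTOR signalling (chromosome 2, 28640993 to 28691172, fold enrichment 3.02 and 3.46 in the 2 KO libraries), the corepressor gene Ctbp1 (3.02 and 3.29), the phosphatase gene Ptpn11 (2.80 and 3.14), the kinase gene Nuak1 (2.34 and 2.80) and Selenos (8.18 and 8.29). Sbno1, Tspyl1, Ttc7 and the neighbours Ncln and S1pr4, which shared a peak, were also named by the rule. The strongest lost peaks lay at Tardbp, which encodes an RNA-binding protein (chromosome 4, 148612382 to 148627084, fold 3.70 and 3.96 in WT), Lcmt1, Nek4, Rpl6 (3.28 and 4.18), Lag3, Chpf2, Capn5, Rps15 (3.13 and 3.41) and the neighbours Nusap1 and Oip5. Allele-specific reads still gave a WT peak at Nuak1, Selenos, Acot9, Med14 and Armcx2, and a KO peak at Tardbp, Chpf2, Rps15, Nusap1 and Oip5.

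On X, 30 of 878 genes without a WT peak were gained (3.42%), against 11.0% of autosomal genes (Fisher's exact test across genes, odds ratio 0.287, adjusted p = 7.4e-15 over 8 tests). Among genes with a peak in at least 1 second-set library, a background chosen later, the shares were 8.75% and 19.7% (odds ratio 0.391, exact p = 6.0e-08). Some autosomes departed from the rest too, by less: over 40 chromosome tests the gained share was 7.42% on chromosome 7 (exact test, adjusted p = 6.9e-05), 7.25% on chromosome 14 (0.0234) and 14.3% on chromosome 10 (0.0171). With no WT peak within 2.5 kb chromosome 7 still passed (exact test, adjusted p = 0.0011), while chromosomes 14 and 10 did not (0.0684 for both). The gained X genes with the strongest peaks were Phka2, Acot9, Brwd3, Med14, a subunit of the Mediator complex, and Armcx2, with fold enrichments of 2.19 to 4.92. The share of X genes with a peak was 7.30% in WT and 13.4% in KO, beside 16.9% and 31.4% of autosomal genes, and the log2 ratio of these shares differed by -0.05 (pooled SD 0.24, exact permutation p = 1). The X allelic skew was -3.93 ± 0.05 in WT and -3.84 ± 0.80 in KO (SD, n = 2 each), a difference of 0.09 that lay within the spread between libraries (exact permutation p = 1).

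None of the 20 gene lists passed the adjusted threshold in KO against WT. The lowest adjusted p, 0.0877, was shared by 2 lists, against 10.6% of other genes gained. The histone acetyltransferase list had 5 of 11 eligible members gained: Kansl3, Kat2b, Kat6b and Ncoa3, and Kat5, which had a WT peak within 2.5 kb. The rRNA synthesis and nucleolus list had 6 of 16: Fbl, which encodes fibrillarin, Nop10, Polr1d, a subunit of RNA polymerases I and III, Taf1a and Ttf1, and Npm1, which had a WT peak within 2.5 kb. In the weaker KO library the −log10 q was 3.94 at Kat6b, 4.97 at Ncoa3, 2.71 at Fbl and 2.67 at Polr1d. The DNA damage response list had 4 of 12 gained (among them Chek1, H2ax and Nbn; Fisher's exact test, adjusted p = 0.353), the sirtuin and histone deacetylase list 4 of 13 (Hdac2, Hdac3, Hdac4 and Sirt6; 0.353) and the imprinted list 0 of 33 (0.353). Ribosomal protein genes were gained at 1 of 23 (Rps19) and lost at 2 of 43 (Rpl6 and Rps15; exact test, adjusted p = 0.420), rRNA synthesis genes were lost at 1 of 12 (Taf1d, which had a KO peak within 2.5 kb; 0.548), and the other 18 lists had 0 members lost. Other gained members were Rlim of the X inactivation centre (1 of 10), Usp9x of the escape list (1 of 11), Brwd3 and Smc1a of the X-linked epigenetic regulators (2 of 17), Foxm1 of the cell cycle (1 of 13), Ddx58 of the interferon response (1 of 22), Hoxa9 and Hoxb13 among 3 of 29 Hox genes, and Sdha among 2 of 5 housekeeping genes. Among cell type markers, 2 of 7 fibroblast genes (Fbn1, and Twist2, which had a WT peak within 2.5 kb) and 2 of 15 neural and melanocyte genes (Map2 and Ncam1) were gained, and 0 of the eligible keratinocyte, immune, endothelial, muscle, and pluripotency and germline markers. Of the members named, Usp9x, Rps19, Hdac3, Chek1, Smc1a, Hoxa9, Hoxb13 and Twist2 had a WT peak of allele-specific reads, and Rps15 and Taf1d a KO peak.

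The differences in genes (0.89 on the log2 scale, pooled SD 0.14) and in coverage (1.00, pooled SD 0.39) exceeded the spread between libraries. Both had an exact permutation p of 0.333, the smallest this design allows. The 1863 genes gained or lost stood beside 128 and 126 for the other ways of parting the same 4 libraries, and with no peak within 2.5 kb in the other group there were 1616 gained and 18 lost genes. With no peak in any of the 3 read classes in the other group there were 1467 gained and 16 lost genes, and the acetyltransferase and rRNA lists passed (Fisher's exact test, adjusted p = 0.0277 for both). That test kept the eligible genes of the main test, including those with a WT peak of allele-specific reads. Neither list passed with no WT peak within 2.5 kb (exact test, adjusted p = 0.240 for both). With peaks of −log10 q of at least 5 neither passed: acetyltransferases had 4 of 15 gained (exact test, adjusted p = 0.111) and rRNA genes 1 of 25. With equal numbers of strongest peaks per library the counts were 761 gained and 179 lost. The histone acetyltransferase list passed (4 of 11, Fisher's exact test, adjusted p = 0.0359) and the rRNA list did not (2 of 16). Without KO replicate 1 the gained count was 3265, and without WT replicate 2 the lost count was 214. The 2 WT libraries correlated at 0.997 in allele ratio over the autosomes, within the 0.972 to 0.998 of libraries of the same clone, so the WT SD is not known to measure spread between clones.

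**Figure D2:**
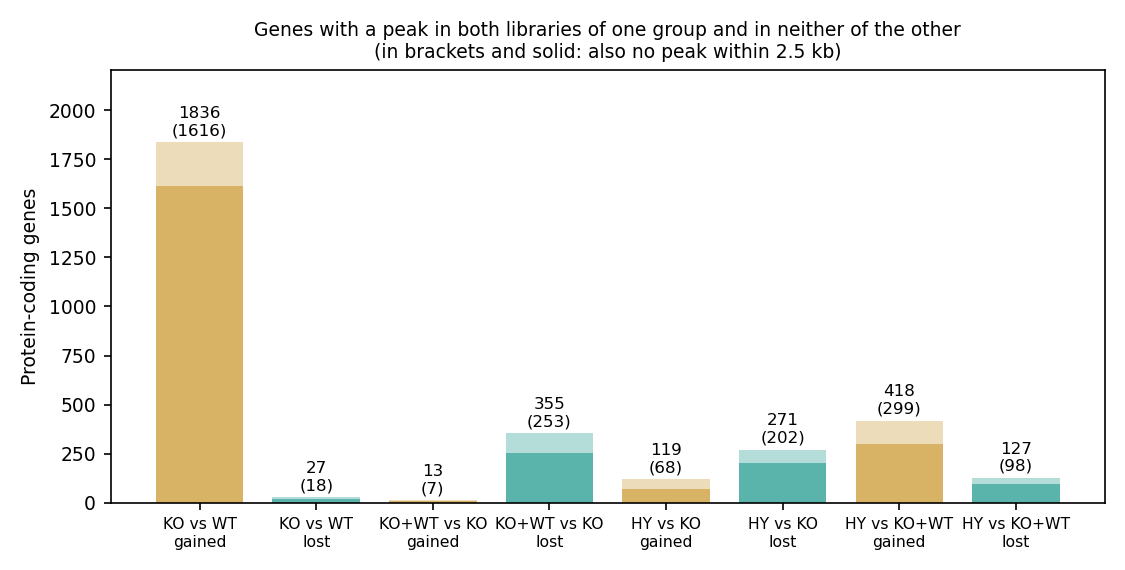
Protein-coding genes with a peak in both libraries of the first-named group and neither of the other (gained) and the reverse (lost), per comparison. The full bar and the upper number count all such genes (1836 gained in KO against WT); the solid part and the number in brackets count those with no peak within 2.5 kb in the other group (1616).

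SIRT7 was added back to KO clones 9 and 22 in the second set, which held no WT library, so a return to WT could not be measured there. KO+WT libraries had a peak at 10159 ± 795 genes and KO libraries at 11653 ± 1045 (SD, n = 2 each), a ratio of 0.872, and peaks covered 35.4 ± 10.8 Mb against 56.7 ± 15.2 Mb. Gained genes numbered 13 and lost genes 355. The strongest lost peaks lay at Commd8 (chromosome 5, 72156576 to 72168189, fold enrichment 6.49 and 7.36 in KO), Pggt1b, a subunit of a protein prenyltransferase (5.52 and 5.97), Slc35g1, the glycolytic enzyme gene Aldoc (5.20 and 5.91), Zfand1, Sardh, Aig1, the neighbours Tstd3 and Usp45, and Ndufb4c. On X, Syap1 (162856843 to 162888462, 6.08 and 6.61), Fgf16 and Capn6 had a peak in KO alone. Of the gained genes, Gbp7, which encodes a guanylate-binding protein (chromosome 3, 142530336 to 142550151), had fold enrichments of 3.95 and 10.2, and Rnf183, Hc, Alcam, Sh3bgrl2, Anapc1 and Brinp1 had 2.91 to 3.55. Apart from Gbp7 (3.45), these gained genes had a −log10 q of 1.27 to 1.75 in the weaker KO+WT library, near the calling threshold. Fgf16 and Capn6 had 1.95 and 1.17 in the weaker KO library. All of these lost and gained calls hold for unassigned reads: allele-specific reads still gave a KO+WT peak at Commd8, Pggt1b, Aldoc, Zfand1, Sardh, Aig1 and Syap1, and a KO peak at Rnf183 and Anapc1.

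Of the 1836 genes gained in KO against WT, which had been chosen for peaks in the shorter first-set KO lists, 97.9% had a peak in both second-set KO libraries, 92.6% in both KO+WT and 95.3% in both HY libraries. Of the 1797 with a peak in both second-set KO libraries, 10 were lost in KO+WT (0.556%), against 3.95% of other genes (odds ratio 0.136). Genes chosen in short lists may have peaks that are seldom missed, so the lower share does not decide whether added SIRT7 acts on them. The muscle marker list was the one of 20 that passed, with 2 of 2 eligible members lost: Des, which encodes desmin, and Myf5, a myogenic transcription factor (Fisher's exact test, adjusted p = 0.0452). Their peaks were near the calling threshold, with a −log10 q of 1.35 to 1.72 at Des and 2.27 to 2.35 at Myf5. With lists of equal length, or peaks of −log10 q of at least 5, 0 muscle markers were eligible and the call ended. Other lost members were Syap1 (escape list, 1 of 20), Rpl37a and Rps18 (ribosomal proteins, 2 of 68), Taf1d (rRNA synthesis, 1 of 26), Hdac11 (1 of 16), Tek (endothelium, 1 of 3) and Nes (neural, 1 of 7), each with an adjusted p of 1 and each with a KO+WT peak of allele-specific reads. The remaining 13 lists had 0 members gained or lost. With peaks of −log10 q of at least 5, another list passed instead: interferon response genes, gained at 2 of 15 (Ifih1 and Isg15; exact test, adjusted p = 0.0013). The interferon list also passed with equal numbers of strongest peaks, gained at 2 of 11 (Isg15 and Oasl1; exact test, adjusted p = 0.0131).

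The difference in genes was -0.20 on the log2 scale (pooled SD 0.12) and in coverage -0.69 (pooled SD 0.42), both with an exact permutation p of 0.333. Clone 22 carried most of both. Its coverage difference was -1.28 and that of clone 9 was -0.09, and for genes the values were -0.37 and -0.03. On X, 1.22% of eligible genes were lost, against 3.44% on autosomes (exact test across genes, adjusted p = 0.0442). The call ended with no KO+WT peak within 2.5 kb (0.915% against 2.45%, exact test, adjusted p = 0.190 over the same 8 tests), and it did not pass over 40 chromosome tests (0.411) or with no peak in any read class (0.591). The X allelic skew was -3.41 ± 0.11 in KO+WT and -3.95 ± 0.41 in KO, and the X share of genes differed by 0.06 (pooled SD 0.02), a sign that turned with peaks of −log10 q of at least 5 (-0.14). The 368 genes gained or lost were hardly more than the 367 that parted clone 22 from clone 9 in the same 4 libraries. With no peak in any of the 3 read classes in the other group there were 8 gained and 129 lost genes, 137 in all against 209 for the split by clone, and the muscle list passed (exact test, adjusted p = 0.00594). With no KO peak within 2.5 kb the gained count was 7. Tjp3, Chrng, Zfp428 and Btbd18 headed the lost genes by −log10 q, and all 4 had a KO+WT peak within 2.5 kb. Without KO clone 9 the lost count was 1695, and without KO+WT clone 22 the gained count was 216.

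HY, an abbreviation not spelled out in the sources used here, was set against KO and KO+WT. HY libraries had a peak at 11181 ± 699 genes and covered 53.7 ± 13.8 Mb (SD, n = 2), within the spread of KO (ratio 0.960 for genes and 0.948 for coverage, exact permutation p = 0.667 for both). The strongest peaks of KO that HY lacked lay at Prkg1, a cGMP-dependent kinase gene (chromosome 19, 30564487 to 31765268, fold enrichment 9.42 and 14.5 in KO), Lyn, a Src-family kinase gene (8.69 and 12.4), Chsy3 (7.11 and 16.7), Gli2, a transcription factor gene of hedgehog signalling (6.79 and 10.3), Inhbb (6.72 and 13.2), Sema3d, Plcl1, Gata6 (6.06 and 7.35), Creb5 and Pxdc1. On X the strongest was Hs6st2, a heparan sulfate sulfotransferase gene (51386637 to 51681705, 9.24 and 17.1), followed by Sytl5, the corepressor gene Bcor (3.63 and 4.97), Pwwp3b and Shroom2. Gained in HY were Jph1 (chromosome 1, 16942104 to 17097922, 7.29 and 14.2 in HY), Kif20b, Ndufb4b, Isoc2a, Irak1bp1, Sdk1, Pdcd2l, Prr15l and Nr2f1, and on X Tsr2. Allele-specific reads still gave a KO peak at Kif20b, Isoc2a, Irak1bp1, Sdk1, Pdcd2l, Prr15l and Tsr2, and a HY peak at Inhbb, Sema3d, Pxdc1 and Pwwp3b.

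In numbers, HY against KO had 119 gained and 271 lost genes, of which 68 and 202 had no peak within 2.5 kb in the other group. The balance turned with peaks of −log10 q of at least 5, with 189 gained and 168 lost genes. On X, 1 of 578 eligible genes was gained (0.173%), against 1.42% on autosomes (exact test across genes, adjusted p = 0.0125). The call ended with no KO peak within 2.5 kb (0.173% against 0.809%, exact test, adjusted p = 0.195 over the same 8 tests), and it did not pass over 40 chromosome tests (0.0623) or with no peak in any read class (0.221). Over those 40 tests chromosome 11 had more gained genes (4.08% against 1.17%, exact test, adjusted p = 9.2e-05) and chromosome 18, with Chsy3 and Gata6, more lost genes (6.23% against 2.48%, 0.0196), both with an adjusted p of 0.0787 with no peak within 2.5 kb in the other group. HY clone 5 had 2568 genome1 and 194 genome2 peaks on chromosome 18. No list passed, and the lowest adjusted p, 0.903, was shared by single members: Ccnd2 (cell cycle, gained 1 of 2), which had a KO peak within 2.5 kb, Myf5 (muscle, lost 1 of 2) and Flt1 (endothelium, lost 1 of 3), and by the interferon response list (gained 1 of 7). Hoxa2 (1 of 14 gained, with a KO peak within 2.5 kb) and Bcor (escape list, 1 of 20, and X-linked regulators, 1 of 16, lost) had an adjusted p of 1, and the other 13 lists had 0 members gained or lost. Allele-specific reads gave a KO peak at Hoxa2 and a HY peak at Flt1. With no peak in any of the 3 read classes in the other group there were 40 gained and 166 lost genes, 206 in all against 272 for the highest other split. The count of 390 genes was below the 499 that parted HY clone 5 with KO clone 22 from HY clone 7 with KO clone 9, and without KO clone 9 the lost count was 1245. With equal numbers of peaks the endothelial list passed (Erg and Flt1 lost, 2 of 2, exact test, adjusted p = 0.0256).

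Against KO+WT, HY had 418 gained and 127 lost genes (299 and 98 with no peak within 2.5 kb), beside 199 and 278 in all for the other ways of parting the 4 libraries. The strongest gained peaks lay at Rilp (chromosome 11, 75510094 to 75513168, fold enrichment 9.18 and 10.3 in HY), Trim65, Eef1akmt1, Jph1, Psrc1, Aldoc (6.86 and 9.10), Med24, Commd8 (6.70 and 9.74), Eps8 and Ndufb4b, and on X at Syap1 (9.29 and 9.35), Arxes2, Capn6 and Ctag2l1. The strongest lost peaks lay at Rbm43 (5.73 and 14.1 in KO+WT), Chsy3, Gli2, Prkg1, Sema3d, Ncald, Lyn, Inhbb, Plcl1 and Prkg2, and on X at Hs6st2 (6.76 and 10.8), Pwwp3b, Sytl5, Gpm6b and Bcor. Allele-specific reads still gave a KO+WT peak at Trim65, Eef1akmt1, Aldoc, Med24, Commd8, Eps8 and Syap1, and a HY peak at Sema3d, Inhbb, Prkg2 and Pwwp3b. With no peak in any of the 3 read classes in the other group there were 157 gained and 82 lost genes, 239 in all against 124 for the highest other split. Gained genes were rarer on X (1.16% against 4.20%, adjusted p = 1.6e-04, exact test across genes) and lost genes more frequent there (3.11% against 1.34%, adjusted p = 0.0400). With no HY peak within 2.5 kb the lost X genes had an adjusted p of 0.0339 over the same 8 exact tests, and over 40 chromosome tests they did not pass (0.200). With no peak in any read class the gained X genes did not pass and the lost ones did (exact tests, adjusted p = 0.361 and 0.0178). On chromosome 11, 41 genes with no KO+WT peak within 2.5 kb were gained (6.23%, against 2.65% elsewhere, exact test, adjusted p = 1.1e-04 over 40 tests).

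No list passed in HY against KO+WT. Ribosomal protein genes came nearest, gained at 3 of 9 (Rpl27, Rpl37a and Rps18; exact test, adjusted p = 0.181), and at 7 of 25 with peaks of −log10 q of at least 5, where the list passed (adjusted p = 0.00675). Single members were gained in the escape (Syap1), histone deacetylase (Hdac11), DNA damage (Parp1), cell cycle (Ccnd2), Hox (Hoxa2), fibroblast (Col6a1) and neural (Nes) lists, or lost in the escape and X-linked regulator (Bcor), interferon (Oasl1), immune (Itgam) and endothelial (Flt1) lists, with adjusted p from 0.280 to 1, and the other 8 lists had 0 members gained or lost. Of the gained members, Rpl27, Ccnd2, Hoxa2 and Col6a1 had a KO+WT peak within 2.5 kb, and all but Rpl27 and Ccnd2 a KO+WT peak of allele-specific reads. Oasl1, Itgam and Flt1 had a HY peak of allele-specific reads. Genes with a peak differed by 0.14 (pooled SD 0.10, exact permutation p = 0.667) and coverage by 0.61 (pooled SD 0.41, p = 0.333). Without KO+WT clone 9 the gained count was 1405, and without KO+WT clone 22 the lost count was 457.

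The X allelic skew of HY was the lowest of the second-set groups, at -5.35 ± 0.42 (SD, n = 2). It lay below KO by 1.40 and below KO+WT by 1.94 (differences of -1.40, pooled SD 0.41, and -1.94, pooled SD 0.30), each with an exact permutation p of 0.333. HY libraries had 2.89 and 2.57 genome1 peaks on X per 100 genome2 peaks, KO libraries 8.77 (clone 9) and 7.69 (clone 22), and KO+WT libraries 10.5 and 17.1. In the first set WT libraries had 8.50 and 8.70 and KO libraries 5.30 and 8.78. HY was measured in clones 5 and 7 and the other groups in clones 9 and 22, so group and clone could not be separated. With peaks of −log10 q of at least 5 the differences were -0.89 and -1.01.

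**Figure D3:**
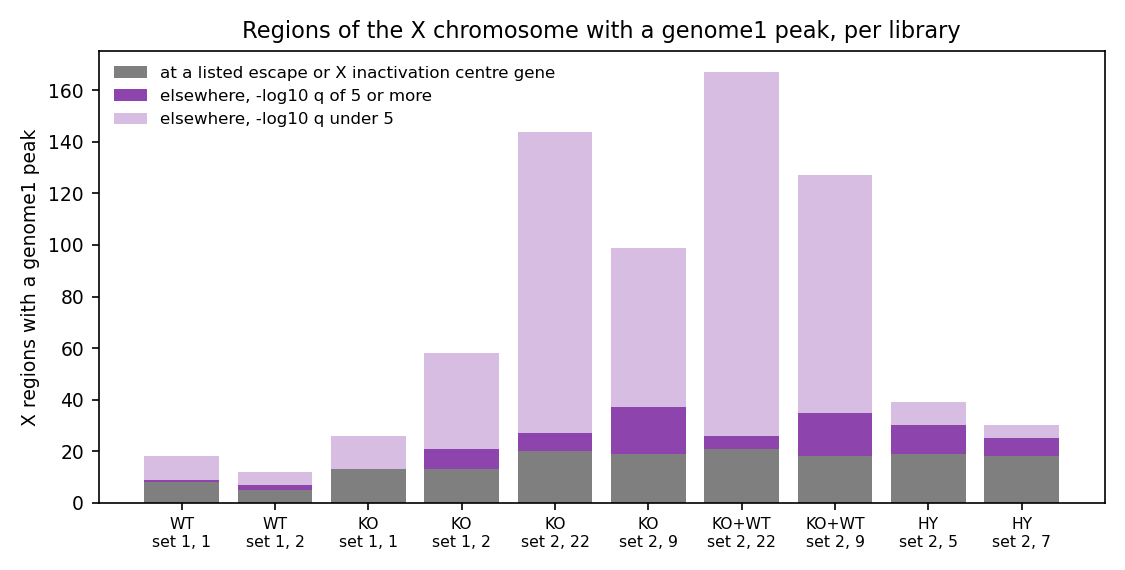
Merged X regions with a genome1 peak per library, split into those at a listed escape or X inactivation centre gene (grey) and others, with a −log10 q of at least 5 (dark) or below (light). Regions elsewhere numbered 80 to 146 in the second-set KO and KO+WT libraries and 12 to 20 in HY, while regions with a −log10 q of at least 5 elsewhere numbered 5 to 18 and 7 to 11.

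**Figure D4:**
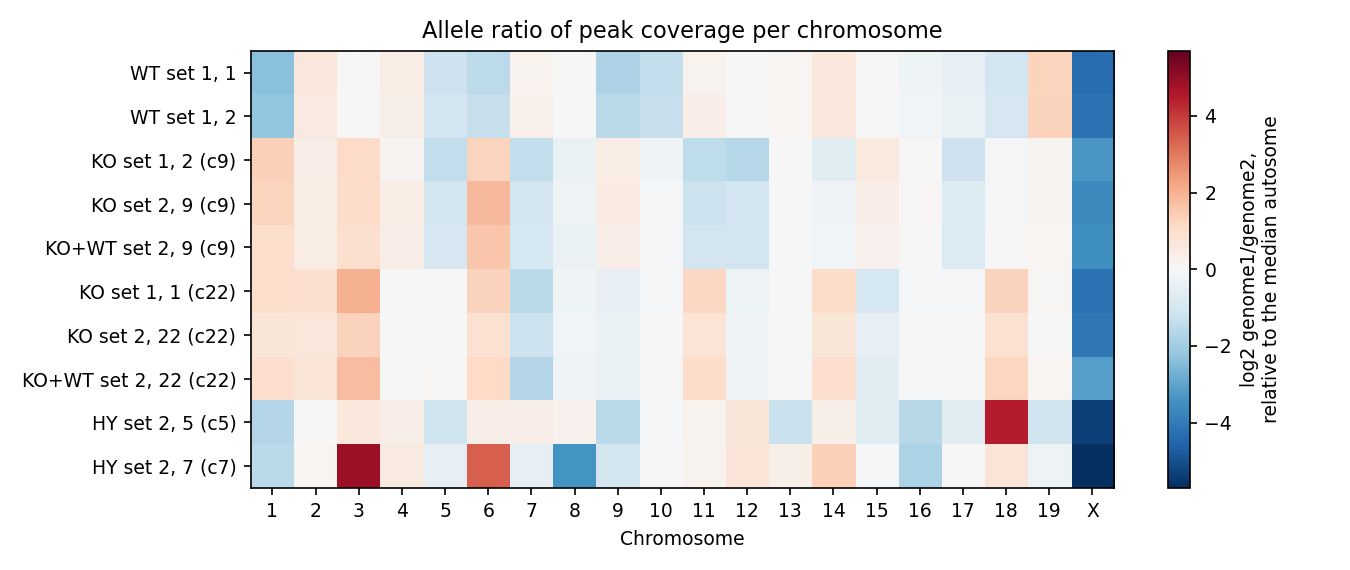
Log2 ratio of genome1 to genome2 peak coverage per chromosome (columns) and library (rows), relative to the median autosome of the library; red is an excess of genome1 and blue of genome2. The X column is blue in all 10 libraries, and single autosomes stand out in HY clone 5 (chromosome 18, 4.47) and HY clone 7 (chromosome 3, 4.88).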

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

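Every test of an explanation in this part was chosen after the result it bears on was seen, except that the predictions for a share of cells with the other X inactive, for lost chromosome copies and for gained chromosome copies were written before those tests were run. Peaks placed on chromosome Y, in lists of female cells, were found in data no comparison used. The second-set lists held 23 (HY clone 5), 28 (HY clone 7), 41 (KO clone 22), 27 (KO clone 9), 30 (KO+WT clone 22) and 16 (KO+WT clone 9) of them. The first-set lists held 0 or 1. Of the 166 peaks, 67 lay in the megabase that starts at 90 Mb, in 6 libraries. The origin of the peaks was not tested and sequence that Y shares with X was not set apart. The peaks do not show that male cells were present.

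The KO-derived libraries of the second set had 80 to 146 genome1 regions on X outside listed escape and X inactivation centre genes, and HY libraries 12 and 20. Per 100 genome2 peaks on X, KO had 8.77 and 7.69 genome1 peaks and HY 2.89 and 2.57. In the first set such regions numbered 10 and 7 in WT and 13 and 45 in KO, and the rates were 8.50 and 8.70 in WT and 5.30 and 8.78 in KO. The WT rates rest on 25 and 18 genome1 peaks, and values of the sets were not compared. Longer peak lists did not account for the lower X allelic skew of HY: with lists of equal length HY stayed below KO by 1.13 (a difference of -1.13). A share of cells with the other X inactive predicted that few of these regions lack a genome2 peak in the same library. Of 414 calls in second-set libraries, at regions found only in KO-derived libraries, 72.5% lacked one. The share ran from 52.2% in KO clone 9 to 92.9% in KO+WT clone 22. Weak calls near the threshold can lack a genome2 peak in any mixture of cells, so this test does not decide the question. In clone 22 at most 7 regions had a −log10 q of at least 5, against at most 11 in HY, as peaks near the calling threshold would give. However, q was lower in clone 22 on autosomes too. There the median −log10 q of genome1 peaks was 2.33 (KO) and 1.88 (KO+WT), against 3.38 and 3.20 in HY. The fixed cut therefore does not decide the question for clone 22. For clone 9, with 18, peaks near the threshold and a true excess cannot be told apart. Absence of SIRT7 protein that re-expression reverses, and no such effect, cannot be told apart: 0 of the 2 clones had fewer regions when SIRT7 was added back, but with a −log10 q of at least 5 the counts went from 7 to 5 in clone 22 and from 18 to 17 in clone 9.

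The number of genes with a peak, higher in KO than in WT, had 1836 genes gained and 27 lost. Gained chromosome copies in the KO clones predicted an excess limited to some chromosomes. Instead, 19 of 19 autosomes had a gained share above the lost share by more than 2 percentage points. So few lost genes left little room for another outcome, and the gained share ran from 7.25% (chromosome 14) to 14.3% (chromosome 10). The excess was thus not limited to some autosomes, but gained copies of single chromosomes were not excluded. Deeper or better enriched KO libraries and a true spread of the mark cannot be told apart. With lists of equal length gained genes still outnumbered lost genes 4.25 to 1, and the reads and enrichment behind each list were unknown.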

How the results depend on the processing

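Alternatives chosen beforehand and those added after the data were seen are given together, and the cause of a change was not tested unless stated. The median autosome as reference of the skew moved no difference by more than the pooled SD (0.51 in KO against WT, 0.54 in KO+WT against KO, -1.66 in HY against KO and -2.20 in HY against KO+WT). Leaving out 1 library kept 71 of 96 results, and counts rose because 1 library then stood for its group. Leave-one-out ranges were 0.67 to 1.34 for coverage in KO against WT and 0.76 to 1.02 for genes. The replicate block left mean differences unchanged (1.00 for coverage and 0.89 for genes in KO against WT), as a mean of pairs does by construction. Its sign-flip exact p was 0.5 or 1, where 0.5 is the smallest that 2 pairs allow, so there was no call it could change. The same holds for crossed pairs of the first set, tried since the paired libraries correlated at -0.125. A paired analysis was not run for switched genes, whose count asks for both libraries. Depth limits all results, since reads per list were unknown.

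With peaks of −log10 q of at least 5, KO against WT gave 1.62 for coverage, 1.38 for genes, -0.57 for the skew and 847 gained genes. KO+WT against KO gave -0.38 for genes, -0.14 for X against autosomes, which reversed, 0.12 for the skew and 7 gained. HY against KO gave 0.0665 for X against autosomes, -0.89 for the skew, 189 gained and 168 lost. HY against KO+WT gave 0.40 for genes, 0.20 for X against autosomes, which reversed, -1.01 for the skew, 639 gained, 29 lost and 1 gene list passing against 0.

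With equal numbers of strongest peaks, KO against WT gave 0.57 for coverage, 0.44 for genes, -0.35 for X against autosomes, 761 gained, 179 lost and 1 list passing against 0. KO+WT against KO gave 26 gained and 160 lost, HY against KO 1 list against 0, and HY against KO+WT 264 gained.

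With coverage of at least 50 percent of a window, KO against WT gave 1.95 for genes, -0.45 for X against autosomes, 804 gained and 8 lost. KO+WT against KO gave -0.48 for genes, -0.0660 for X against autosomes, which reversed, and 535 lost, HY against KO 0.19 for X against autosomes and 179 lost, and HY against KO+WT 0.49 for genes, 0.26 for X against autosomes, which reversed, 764 gained and 39 lost.

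Pooled lists gave 2.71 for coverage, 1.46 for genes, 0.40 for X against autosomes and 5591 gained in KO against WT. Whole gene spans gave 0.61 for genes in KO against WT, and 0.0134 for X against autosomes and 33 gained in KO+WT against KO. In that comparison windows of 2.5 kb gave 0.0244 and 23 gained, the union of read classes 0.0191 and 48 gained, and lists of all reads -0.0138, which reversed, and 212 lost. Lists of all reads gave 0.0046 for X against autosomes in HY against KO+WT, which reversed. Asking for no peak within 2.5 kb gave 7 gained in KO+WT against KO and 68 in HY against KO. Asking for no peak in any of the 3 read classes gave 16 lost and 2 lists passing in KO against WT, 8 gained and 129 lost in KO+WT against KO, 40 and 166 in HY against KO, and 157 and 82 in HY against KO+WT. The number of X-linked genes gave a skew difference of 0.83 in KO against WT, 0.0355 in KO+WT against KO and -1.09 in HY against KO+WT. Overlap by 50 percent of both peaks gave 0.0529 for libraries of the same group over others of the set, against 0.0246.

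Leaving out 1 library gave these ranges of switched genes, which rose since fewer libraries had to concur. In KO against WT gained genes ranged from 2150 (without WT replicate 1) to 3265 (without KO replicate 1), and lost genes from 52 (without KO replicate 1) to 214 (without WT replicate 2). In KO+WT against KO the gained count reached 216 without KO+WT clone 22, and lost genes ranged from 498 (without KO+WT clone 22) to 1695 (without KO clone 9). In HY against KO they ranged from 201 (without KO clone 9) to 567 (without HY clone 7) and from 388 (without HY clone 7) to 1245 (without KO clone 9). In HY against KO+WT they ranged from 578 (without KO+WT clone 22) to 1405 (without KO+WT clone 9) and from 166 (without HY clone 7) to 457 (without KO+WT clone 22).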

Other observations

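The tests in this part were chosen after the results were seen, and only the prediction for lost chromosome copies was written before its test was run. At the 37 listed imprinted genes, peaks called on reads of a single parental genome fell at the gene ends on genome1 alone at 8, on genome2 alone at 2, on both at 10 and on neither at 17. Impact had a genome1 peak at a gene end in 6 libraries and a genome2 peak in 0, Peg10, Sgce and Plagl1 in 5 and 0, Kcnq1ot1, the antisense RNA of the Kcnq1 cluster, in 4 and 0, and Zrsr1 in 3 and 0. Grb10, an adaptor protein of growth factor receptors, and Igf2r, the receptor that clears IGF2, were the reverse, with a genome2 peak in 6 libraries and a genome1 peak in 0. Within the gene the sides were not as strict: genome1 peaks lay inside Igf2r in 9 libraries and inside Grb10 in 5, and genome2 peaks inside Plagl1 in 5, Sgce in 2 and Kcnq1ot1 in 1. Some counted libraries leaned to genome1 over the whole chromosome. These were HY clone 5 on chromosome 18, where Impact lies (2568 genome1 and 194 genome2 peaks), and HY clone 7 on chromosome 6, where Peg10 and Sgce lie (2573 and 309). A genome1 peak alone in these libraries does not bear on imprinting. Among the 10 with both, Mirg had each in 7 libraries and Zdbf2 each in 5, and H13 had 3 genome1 and 9 genome2. H19, Igf2 and Dlk1 had neither.

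When both HY libraries were set against all 4 KO-derived libraries of the second set, a grouping added after the data were seen, 84 genes had a peak of unassigned reads only in both HY and 95 only in all 4 others. Hoxa2, a homeobox gene, and the cyclin gene Ccnd2 were on the first side, both with a KO-derived peak within 2.5 kb, and Bcor, the endothelial receptor gene Flt1, Gli2, Hs6st2 and Chsy3 on the second. Allele-specific reads gave a KO-derived peak at Hoxa2 and a HY peak at Flt1. In the first set Gli2 and Hs6st2 had a peak in 0 WT and 0 KO libraries, and Chsy3 in 0 WT and 1 of 2 KO libraries. Other genes of that side differed: Lyn and Inhbb had a peak in 0 WT and 2 KO libraries, and Sema3d in 2 and 2. Of the 15 ways to part 2 of the 6 libraries from the rest, the pair HY clone 5 and KO clone 22 gave 313 such genes against 179 for HY.

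Msn, which encodes moesin, had a genome1 peak on X in 6 of 6 KO-derived libraries and 0 of the 4 others, and was picked out after the values were seen. The 6 libraries came from 2 clones, and the 4 others were first-set WT and second-set HY libraries. Of the 418 merged genome1 regions on X, 375 were found only in KO-derived libraries. Of these, 24 were found in both clones and 3 in all 6 libraries. Most calls were weak: outside listed escape and X inactivation centre genes, the median −log10 q was 1.32 to 2.71 in the KO-derived libraries.

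Whole autosomes were out of balance between genome1 and genome2 in single clones. HY clone 5 had 2568 genome1 and 194 genome2 peaks on chromosome 18, and HY clone 7 had 2726 and 114 on chromosome 3, 2573 and 309 on chromosome 6 and 457 and 2813 on chromosome 8. Mapping bias was argued against, since the allele ratio of chromosome 18 differed between libraries by up to 5.56 on the log2 scale. In HY clone 5, 100% of the 5 Mb bins of chromosome 18 had more genome1 coverage, which chromosome copies lost in the clone would give. The chromosome was picked for its large excess of genome1 peaks, which left little room for another outcome. Copy number was not measured, so this test does not establish a lost copy. The imbalance went with clone identity: libraries of the same clone correlated at 0.972 to 0.998 over the autosomes (exact p = 0.000476 over 4200 regroupings). The WT pair correlated at 0.997 and the HY pair at 0.351.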
